A study of Mus musculus with 6 samples.

How the data were processed

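Chromatin contacts were measured by Hi-C in P19 cells, a mouse embryonal carcinoma line that can be driven towards neurons with retinoic acid. Hi-C ligates DNA ends that lie close together in fixed nuclei and counts the junctions by paired sequencing. The 6 libraries fell into 3 groups of 2 replicates: untreated cells (T0) and cells treated with 1e-06 M all-trans retinoic acid (ATRA) for 6 h (T6) or 48 h (T48). The series has no untreated cells at 6 h or 48 h, so ATRA cannot be told apart from time in culture. Groups and replicate numbers came from the sample titles. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Per the labels' protocols, crosslinked chromatin was digested, the ends were filled in with a biotinylated nucleotide and ligated, and junctions were captured on streptavidin beads and amplified by PCR. Per the submitters' processing notes, CASAVA 1.8.2 and Bowtie2 were used and the genome build was mm9. The restriction enzyme, the caller of significant interactions, its threshold and any correction for bin coverage were not given in the sources used here.

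The authors deposited a single list of pairs of 5 kb bins with a raw count of read pairs per library, per the file headers. The submitters name its content as significant interactions found in both replicates. It held 3,654,014 pairs, all within a chromosome, 5 kb to 10 Mb apart, with 0 duplicated pairs. In the deposited table both replicates of a time point always had a count above 0 or a count of 0 together, and the lowest count above 0 was 3. A 0 was therefore read as a pair not listed at that time point, never as a measured absence of contact. At 5 kb the lowest listed count of T0 replicate 1 was 29, and it was the same on all 20 nuclear chromosomes. The 4 pairs on the mitochondrial chromosome were left out of all comparisons. The table lists interactions for a time point and not for a library, so numbers, overlaps and distances of listed pairs have no replicate error. The sum of listed counts per library was 50,154,643 and 29,644,373 at T0, 40,561,360 and 23,003,295 at T6, and 43,500,876 and 29,554,481 at T48, for replicates 1 and 2. These sums cover listed pairs alone and are not the sequencing depth. Read pairs carry no molecular identifiers, so intervals of shares cover counting error only.

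Lists were compared by the number of pairs, by shared pairs (both bins identical), and by the Jaccard index, which is shared pairs over all pairs of both lists. Chance overlap was described by redrawing pairs 100 times within each chromosome at the same distances. Retention of pairs was given by their count as a multiple of the lowest count listed for that distance and library, with 95% Wilson intervals. Long interactions were those of at least 500 kb. Anchor degree is the number of interactions listed for a bin. Its log2 ratio between time points was scaled to the length of the lists, with 0.5 added. The anchor bins named in the report were the 5 with the largest gain and the 5 with the largest loss per comparison among bins with at least 20 interactions over the 3 time points, 1 per 500 kb. No mm9 annotation was used here, so no gene is named and the planned comparison of gene lists was not made.

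Interaction strength was tested on the 542,645 pairs listed at all 3 time points with edgeR 4.0.16 in R 4.3.3. TMM factors, filterByExpr (496,203 pairs kept) and the quasi-likelihood F test were applied to all 6 libraries in 1 fit, with p-values two-sided and adjusted by Benjamini-Hochberg at 0.05. DESeq2 1.42.0, DESeq2 size factors, no filter, a replicate block and leaving out each library were alternatives. These tests, the alternatives for the lists and the rule for named bins were set before the data were examined. After the interaction test had given 0 calls, counts were also summed per window and tested in the same way. Windows of 25, 50 and 100 kb and pairs of 25 kb bins were tried, with and without the replicate block, before windows of 50 kb were chosen, so the window calls are exploratory. Each pair was counted in the window of each of its bins, and 49,387 windows passed filterByExpr. A pair with both bins in 1 window entered that window once per bin, so short pairs weigh more in the window counts. The sum over windows was 58,000,692 in T0 replicate 1, against 29,000,604 over pairs. A fit with such pairs counted once was not run, and all window values below rest on these sums. The CPM of a window is relative to the sum over all windows. A stricter list, with counts of at least 1.5 times the lowest listed in both replicates, and offsets per distance class were also added after the data were seen.

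The fits were tested on simulated counts with 200 changed features at the observed means and library sizes. Dispersions followed the fitted trend over the mean, with no spread around it and no effect shared by libraries of the same number. In simulated T48 over T0 comparisons of 489,320 interactions, edgeR recovered 2.99% of interactions changed 1.5-fold, 5.97% of those changed 2-fold and 77.3% of those changed 4-fold. For 49,372 windows, 47.8%, 82.1% and 97.0% were recovered. There was 1 false call among the interactions and 4 among the windows. In the simulated T6 over T0 comparison, which held no change, 4.89% of interactions and 4.91% of windows had an unadjusted edgeR p under 0.05. The data had 3.17% and 1.75% in the same comparison, so the recovery rates may not hold for them. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and version 1.17.8 of data.table read the counts in R. Intervals of the tests in the closing section came from 1000 bootstrap draws.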

Results

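The data were lists of chromatin interactions in P19 cells before and during the first 48 h of ATRA treatment, a model of early neuronal differentiation. An interaction is a pair of 5 kb bins that the authors called significant in both replicates of a time point. On the nuclear chromosomes 1,911,467 interactions were listed at T0, 1,617,863 at T6 and 1,825,848 at T48, in 2 libraries each. The median count of a listed pair was 14 and 9 in the T0 libraries, 13 and 8 in the T6 libraries, and 12 and 9 in the T48 libraries, so single pairs were measured with few reads. The comparisons asked which contacts differed between undifferentiated cells, the early response at 6 h and the cells at 48 h.

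Contacts of a few bins were listed throughout the time course, and most longer pairs were listed at 1 time point. All 3 lists shared 542,645 pairs, with a median distance of 10 kb. A further 903,310 pairs were listed only at T0, 698,544 only at T6 and 893,633 only at T48, with median distances of 185, 210 and 235 kb. T0 and T6 shared 768,953 pairs (Jaccard index 27.9%), T0 and T48 shared 781,849 (26.5%), and T6 and T48 shared 693,011 (25.2%). These overlaps were 2.11, 1.92 and 1.95 times those of pairs redrawn at the same distances. Among pairs over 20 kb apart the excess was 4.96, 4.58 and 4.83 times.

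Retention of an interaction went with its count. Of T0 interactions between 20 and 500 kb with counts under 1.5 times the lowest listed, 23.9% were listed again at T48 (95% Wilson interval 23.8 to 24.0%). At counts of 3 times the lowest or more, 89.7% were (interval 89.1 to 90.2%). The corresponding shares at T6 were 25.04% and 93.0%. In a wider match, pairs of 2 lists counted as shared when each anchor of the first lay within 1 bin of the corresponding anchor of the second. The Jaccard index was then 60.9% for T0 and T6, 58.5% for T0 and T48, and 56.9% for T6 and T48. The overlap of redrawn pairs was not computed for this wider match, so these indices have no chance level beside them.

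**Figure D1:**
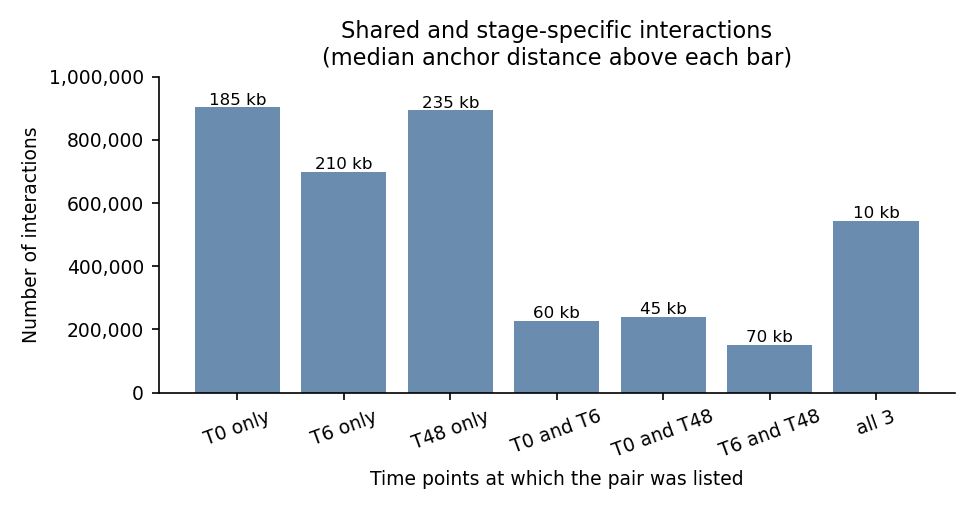
Number of interactions (vertical axis) by the time points at which the pair of bins was listed (horizontal axis), with the median anchor distance above each bar. Pairs listed at all 3 time points had a median distance of 10 kb, against 185 to 235 kb for pairs listed at 1 time point; the lists are joint for both replicates and have no error bars.

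Long interactions made up more of the list at 48 h. Pairs of at least 500 kb numbered 220,984 at T0 (11.6% of the list), 183,708 at T6 (11.4%) and 277,202 at T48 (15.2%). The share was above that of T0 on 20 of 20 chromosomes at T48 and on 4 of 20 at T6. Between 1 and 2 Mb, T48 listed 1.48 times as many pairs as T0, whereas between 20 and 50 kb it listed 0.812 times as many. The median distance was 75 kb at T0 and T6 and 85 kb at T48. The T6 minus T0 difference of the share, -0.206 percentage points, turned to 0.123 in a stricter list with counts of at least 1.5 times the lowest listed.

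In counts, pairs of at least 500 kb held 2.12% and 3.25% of the listed count in the T0 libraries, 2.13% and 3.55% in the T6 libraries, and 2.98% and 4.04% in the T48 libraries, for replicates 1 and 2. The means were 2.68% ± 0.804, 2.84% ± 1.00 and 3.51% ± 0.750 (SD, n = 2), so the values of T0 and T48 overlapped, while the T48 value was higher within each replicate number. With 2 libraries against 2, no two-sided exact permutation test can go below p = 0.333. Among the pairs listed at all 3 time points, which leave out every pair that entered or left the list, long pairs held 0.699% ± 0.376 of the count at T0 and 0.698% ± 0.332 at T48 (SD, n = 2).

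**Figure D2:**
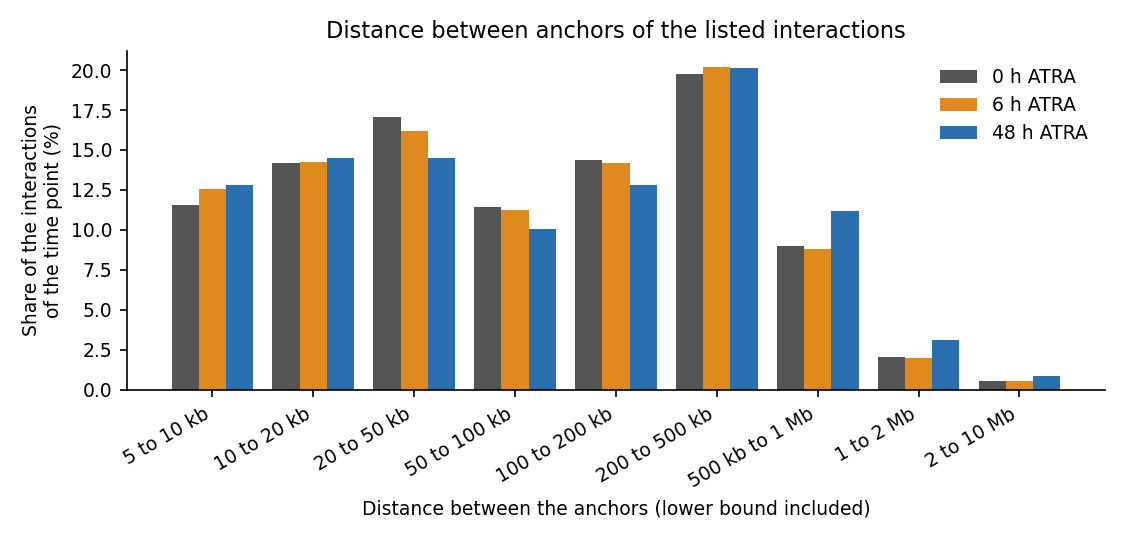
Share of the interactions of each time point (%, vertical axis) by the distance between the anchors (horizontal axis), for 0, 6 and 48 h of ATRA. The 48 h list holds 11.2% of its interactions between 500 kb and 1 Mb, against 8.98% at 0 h, and 14.5% between 20 and 50 kb, against 17.1% at 0 h; bars are list totals without replicates.

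After 6 h, no interaction and no 50 kb window passed the main edgeR test for a change in count, which has no replicate block. The interactions with the lowest p, named here after their values were seen, included 1 on chromosome 6 between the bins centred on 122,827,500 and 122,832,500, with counts of 46 and 26 at T0, 181 and 82 at T6, and 35 and 26 at T48 (log2 T6 over T0 2.01, edgeR adjusted p = 0.676). Another joined the bins of chromosome 3 centred on 84,077,500 and 84,107,500, with counts of 88 and 49 at T0, 25 and 14 at T6, and 21 and 14 at T48 (log2 -1.63, edgeR adjusted p = 0.676). edgeR called 0 of 496,203 interactions, with 15,733 (3.17%) at an unadjusted p under 0.05, and DESeq2 called 1, between the bins of chromosome 4 centred on 106,852,500 and 106,857,500 (DESeq2 adjusted p = 0.0176, edgeR adjusted p = 0.892). Among 49,387 windows edgeR called 0, with 864 at an unadjusted p under 0.05, and DESeq2 called 20. With the replicate number as a block, edgeR called 11 windows, 6 higher and 5 lower, and 0 interactions. The labels give no common origin of libraries with the same number, but the differences between replicates correlated across interactions at 0.349 between T0 and T6. In the simulation, 5.97% of interactions changed 2-fold were recovered in a T48 over T0 comparison without a replicate block. The simulated libraries shared no replicate effect, so that rate is only a guide to these data. The 0 calls cannot be read as an absence of 2-fold changes in single pairs.

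After 48 h, counts rose in 2 windows of 50 kb, both on chromosome 1, and fell in 9. The counts were not corrected for bin coverage, so a change in the coverage of a window cannot be told apart from a change of contact. Between 196,500,001 and 196,550,000 of chromosome 1, the CPM (edgeR counts per window, relative to the sum over all windows) rose from 33.6 ± 0.638 to 72.1 ± 0.116 (SD, n = 2; log2 1.10, SE 0.057, edgeR adjusted p = 0.0180). Between 170,750,001 and 170,800,000 it rose from 11.4 ± 0.787 to 30.3 ± 0.599 (log2 1.41, SE 0.086, edgeR adjusted p = 0.0192), and the listed interactions of that window numbered 30 at T0, 27 at T6 and 136 at T48. The strongest falls were on chromosome 8 between 114,250,001 and 114,300,000 (log2 -1.10, edgeR adjusted p = 0.0192), chromosome 6 between 122,300,001 and 122,350,000 (log2 -1.06, edgeR adjusted p = 0.0192) and chromosome 1 between 122,150,001 and 122,200,000 (log2 -1.04, edgeR adjusted p = 0.0180). A second window of that part of chromosome 1, between 122,500,001 and 122,550,000, also fell (log2 -0.87).

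The other windows that fell lay on chromosome 9 from 36,800,001 (log2 -0.97), chromosome 19 from 46,500,001 (-0.86), chromosome 5 from 36,400,001 (-0.81), chromosome 1 from 54,500,001 (-0.76) and chromosome 2 from 92,250,001 (-0.72). In 3 of the 9, the T6 values were already near those of T48. The log2 ratio of T6 over T0 was -0.89 on chromosome 5, -0.71 on chromosome 19 and -0.56 on chromosome 2 (edgeR adjusted p = 0.142, 0.235 and 0.235, and 0.0129, 0.0187 and 0.0284 with the replicate block). In the other 6 it lay between -0.10 and 0.03. Within replicates 1 and 2 the log2 ratio of T48 over T0 was 1.12 and 1.08 in the window of chromosome 1 from 196,500,001 and -1.12 and -1.08 in that of chromosome 8, and each of the 11 windows had the same sign in both. The windows were chosen by a test on the same libraries, so the shared sign is no further support. With any 1 of the 6 libraries left out edgeR called 0 windows (lowest adjusted p per fit between 0.0772 and 0.274), also where that library was of T6. The log2 ratios of the 11 windows moved by at most 0.072 in these fits, which have 2 residual degrees of freedom in place of 3. Their SE lay between 0.061 and 0.120, against 0.057 to 0.086 in the main fit, so the lost calls do not show that a change rests on 1 library. Windows of 100 kb and pairs of at least 15 kb also gave 0 calls in edgeR. There, 2360 of 25,108 windows (9.40%) and 3640 of 40,530 (8.98%) had an unadjusted p under 0.05. DESeq2 called 527 of the 49,387 windows, 80 of them higher and 447 lower. An unadjusted p under 0.05 was given to 4289 of these windows (8.68%) by DESeq2 and to 3874 (7.84%) by the main edgeR fit. With the replicate block edgeR called 185, 29 higher and 156 lower.

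Single interactions gave 0 calls at 48 h in edgeR, with 27,390 (5.52%) at an unadjusted p under 0.05, and 94 in DESeq2, 46 higher and 48 lower. With the replicate block edgeR called 1, between the bins of chromosome 2 centred on 98,502,500 and 98,507,500, named for its call, with counts of 29,401 and 53,213 at T0, 42,623 and 64,560 at T6, and 13,504 and 28,655 at T48 (log2 T48 over T0 -0.92, edgeR adjusted p = 0.00859 with the block and 0.972 without it). The median listed count at 5 kb was 81 and 44 in the T0 libraries, so this pair lay far outside the usual range. Replicate 2 held more of it than replicate 1 at each time point, although the sums of listed counts were smaller there. The cause of these counts was not tested, so the call need not be a fall of contact. The lowest edgeR p, chosen after its value was seen, belonged to the pair of bins on chromosome 1 centred on 196,512,500 and 196,522,500, in the window that rose most firmly. Its counts were 45 and 28 at T0, 44 and 26 at T6, and 315 and 174 at T48 (log2 T48 over T0 2.82, edgeR adjusted p = 0.281).

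**Figure D3:**
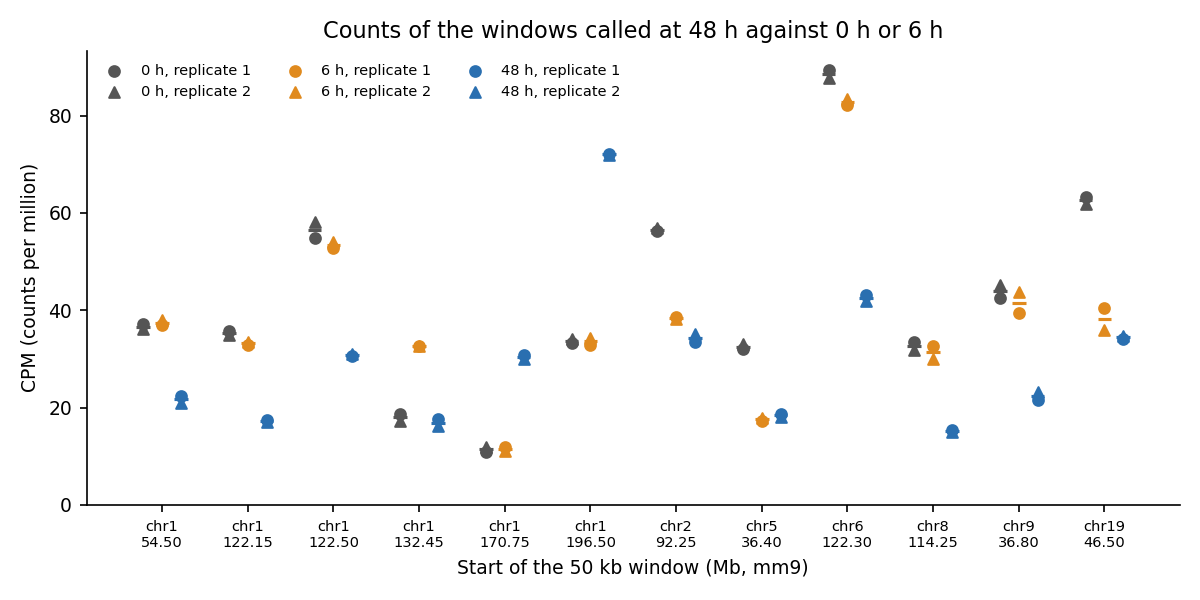
CPM of the 12 windows called at 48 h against 0 h or 6 h (vertical axis) by the chromosome and start of the window (horizontal axis, Mb). Circles are replicate 1, triangles replicate 2 and short lines the means; the window of chromosome 1 from 196.5 Mb has a mean of 33.6 at 0 h and 72.1 at 48 h.

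Chromosome 1 held a smaller part of the list at 48 h. It carried 7.53% of the interactions at T0, 7.51% at T6 and 6.78% at T48. Its pairs of 20 to 100 kb changed in number by -29.4% between T0 and T48, and those from 500 kb by 14.2%, against -21.6 to -7.49% and 19.3 to 33.2% on the other chromosomes. Of the 50 windows of 1 Mb with the lowest log2 ratio of T48 over T0, 32 lay on chromosome 1, which has 168 of 2455 such windows. Of the 50 with the highest ratio, 6 lay on chromosome 1, 10 on chromosome 14 and 8 on chromosome X. Counts were compared in its pairs listed at all 3 time points, as the mean log2 ratio of T48 over T0 relative to autosomes. The ratio was -0.042 in replicate 1 and 0.018 in replicate 2 under 20 kb. It was -0.079 and 0.040 at 20 to 100 kb, and -0.086 and 0.021 at 100 to 500 kb. The counts of pairs that stayed listed thus went opposite ways in the 2 replicates. A listed pair must be significant in both replicates, and whether the smaller list rests on 1 library was not tested.

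Pairs on chromosome X under 20 kb apart had lower counts at 48 h than autosomal pairs. Relative to autosomal pairs, the mean log2 ratio of T48 over T0 was -0.12 ± 0.063 (SD, n = 2), with -0.17 within replicate 1 and -0.080 within replicate 2. That of T6 over T0 was 0.0015 ± 0.015. Chromosome 14 followed at -0.052 ± 0.019 under 20 kb. The fall on chromosome X was not limited to short pairs. Its T48 over T0 ratios relative to autosomes within replicates 1 and 2 were -0.196 and -0.115 at 20 to 100 kb, and -0.205 and -0.137 at 100 to 500 kb. The number of listed chromosome X pairs under 20 kb went the other way, from 14,971 at T0 to 18,245 at T48, a log2 ratio of 0.28 relative to autosomes. This number also takes in pairs that were not listed at every time point. Chromosome X also differed between replicates of 1 time point, by a log2 of -0.20 at T0, -0.23 at T6 and -0.093 at T48 (replicate 2 over replicate 1).

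**Figure D4:**
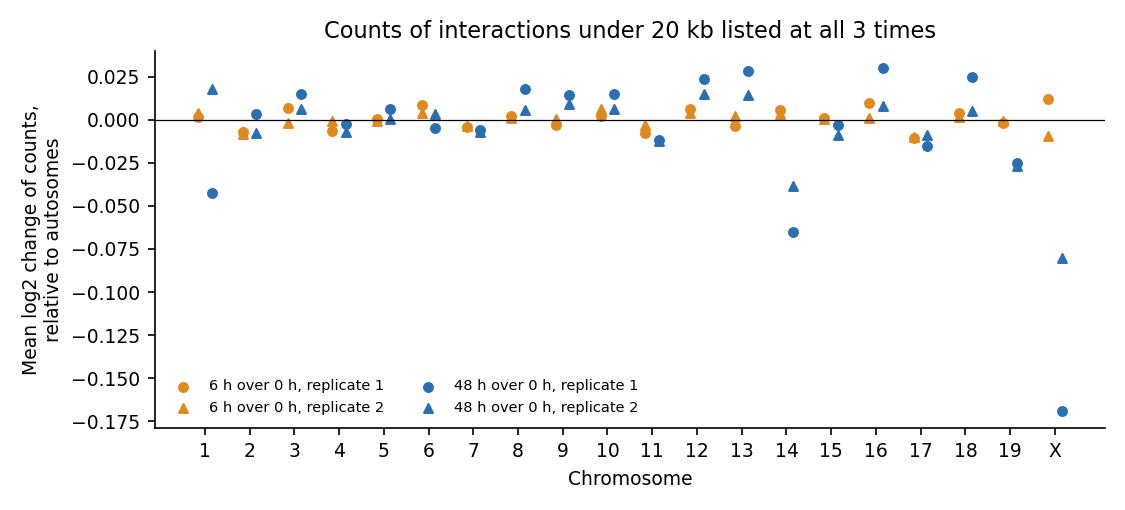
Mean log2 change in the count of pairs under 20 kb listed at all 3 time points, relative to autosomes (vertical axis), per chromosome (horizontal axis). Circles are replicate 1 and triangles replicate 2; chromosome X lies at -0.17 and -0.080 for 48 h over 0 h, below every autosome in both replicates.

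Between 6 h and 48 h, 2 windows rose and 6 fell, in a comparison that shares its T48 libraries with that against T0. The windows of chromosome 1 from 196,500,001 and from 170,750,001 rose by log2 1.10 and 1.40 (edgeR adjusted p = 0.0264 for both). A window of chromosome 1 between 132,450,001 and 132,500,000 fell from 32.6 ± 0.031 to a CPM of 16.9 ± 0.886 (SD, n = 2; log2 -0.94, edgeR adjusted p = 0.0475). Its value at T0 was 18.02 ± 0.955, and the T6 over T0 ratio was log2 0.85 (edgeR adjusted p = 0.152, and 0.0129 with the replicate block). The other falls were on chromosome 8 from 114,250,001 (log2 -1.04), chromosome 6 from 122,300,001 (-0.96), and chromosome 1 from 122,150,001 (-0.95), 122,500,001 (-0.79) and 54,500,001 (-0.79). Within replicates 1 and 2 the ratio was 1.37 and 1.44 in the window from 170,750,001 and -0.89 and -1.001 in that from 132,450,001, and each of the 8 windows had the same sign in both. Here too the windows were chosen by a test on the same libraries.

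As for T48 over T0, leaving out any 1 library left 0 windows called in edgeR (lowest adjusted p per fit between 0.0957 and 0.346), while the log2 ratios of the 8 windows moved by at most 0.062, and by at most 0.00044 where that library was of T0. For single interactions edgeR called 0, with 25,105 (5.06%) at an unadjusted p under 0.05, and DESeq2 called 74, 36 higher and 38 lower. With the replicate block edgeR called 1, the same pair of chromosome 2 (log2 -1.52, edgeR adjusted p = 0.000129 with the block and 0.993 without it). For windows edgeR had 3082 at an unadjusted p under 0.05 and DESeq2 called 337, 64 of them higher and 273 lower. With the replicate block edgeR called 161, 20 higher and 141 lower.

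The number of interactions per anchor bin was kept in part across the time course. Over 262,315 bins with at least 20 interactions, Spearman's rho across bins, which are not replicates, was 0.641 between T0 and T6 and 0.531 between T0 and T48. In the stricter list, rho was 0.388 and 0.140. By the fixed rule, the largest gains at 48 h over 0 h lay in bins with 0 interactions at T0, such as chromosome 14 from 100,330,001 (0, 1 and 34 interactions at T0, T6 and T48) and chromosome X from 163,240,001 (0, 0 and 32). The largest loss was on chromosome 13 from 58,745,001 (32, 3 and 0). At 6 h the first gain was on chromosome 14 from 113,440,001 (0, 27 and 17) and the first loss on chromosome X from 110,740,001 (32, 0 and 18). The rule named 30 bins over the 3 comparisons, where a bin named in more than 1 comparison counts in each, and 29 of these had 0 interactions at a time point, so the counts of pairs listed at all 3 time points cannot show whether the contacts of those bins changed.

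The bin with the largest gain of T48 over T6 stood on chromosome 1 between 171,165,001 and 171,170,000, with 4, 1 and 130 interactions. Its window had a log2 ratio of T48 over T6 of 0.84 (edgeR adjusted p = 0.508). Nearby, in bins chosen after their values were seen, the bin from 170,765,001 had 4, 5 and 108 interactions, and that from 170,970,001 had 3, 4 and 104. The bin from 170,995,001 was listed with 87, 70 and 127. The bin from 170,765,001 lies in the window from 170,750,001 whose counts rose at 48 h, a test that rests on 6 pairs under 20 kb and 1 from 100 kb. For the T48 interactions of the 3 bins with few at T0, the median distance was between 248 and 285 kb, and partners lay on both sides.

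**Figure D5:**
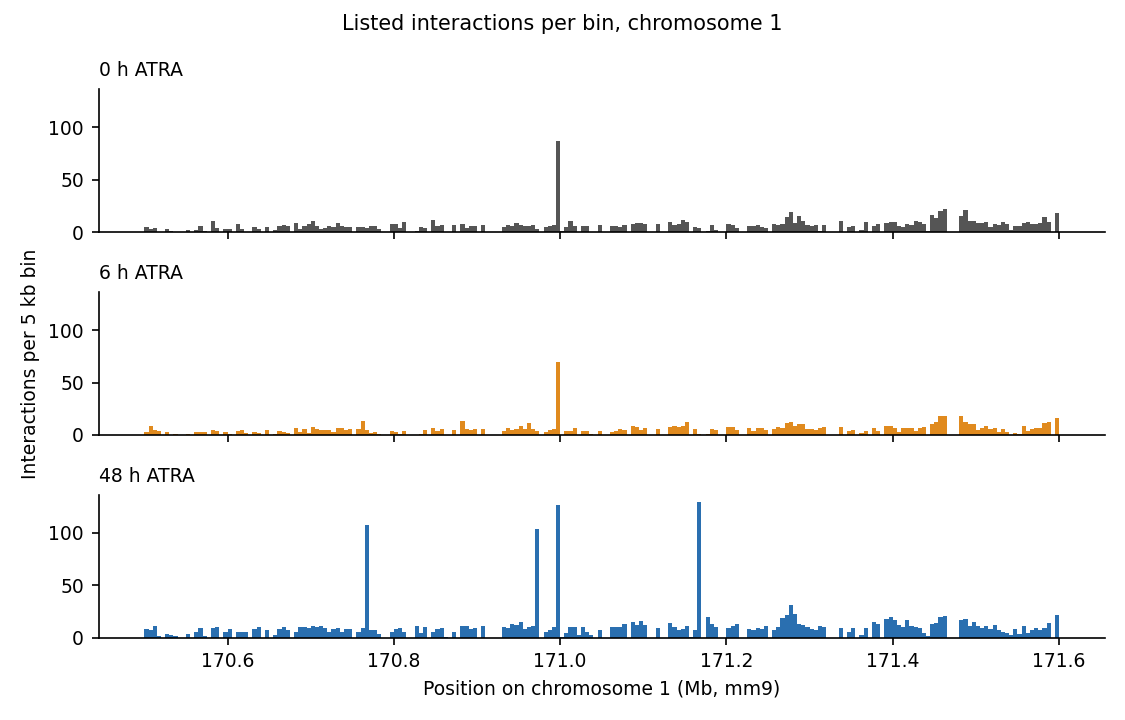
Listed interactions per 5 kb bin (vertical axis) along chromosome 1 (horizontal axis, Mb, mm9) at 0, 6 and 48 h of ATRA. Bins from 170,765,001, 170,970,001 and 171,165,001 hold 108, 104 and 130 interactions at 48 h and at most 5 at 0 h and 6 h, while the bin from 170,995,001 holds 87, 70 and 127; lists are joint for both replicates.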

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

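The test of 50 kb windows was chosen only after the planned test of single interactions had been seen to give 0 calls. In 8 windows the counts differed between T48 and T6 in edgeR, which is a test of whether the change from T0 differs between the times. The clearest departure from a steady course was the window of chromosome 1 between 132,450,001 and 132,500,000, with a CPM of 18.02, 32.6 and 16.9 at T0, T6 and T48, and 49, 90 and 39 listed interactions. The remaining 7 had T6 values within a log2 of 0.10 of T0. With any 1 library left out, 0 of the 8 were called, with the same direction in all 114 refitted values over both comparisons that involve T48, and the log2 ratios of the 8 moved by at most 0.062.

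On the mitochondrial chromosome, which entered no comparison, 4 pairs of bins were listed in every library, above the limit that a count of 0 allows. They held 2263 and 2611 counts at T0, 2998 and 2491 at T6, and 967 and 2273 at T48, or between 0.00222% and 0.0108% of the listed count of a library.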

How the results depend on the processing

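The stricter list, the offsets per distance class, the pairs of 25 kb bins and all tests of windows were chosen only after the data were seen; the other alternatives were set beforehand. Numbers of listed pairs relative to T0 were 0.846 at T6 and 0.955 at T48. They were 0.833 and 0.935 for distances of at least 15 kb, 0.845 and 0.952 on autosomes only, and 0.770 and 0.939 in the stricter list with counts of at least 1.5 times the lowest listed. With 1 chromosome left out they ranged from 0.845 to 0.847 and from 0.952 to 0.963. The Jaccard indices (T0 and T6, T0 and T48, T6 and T48) were 19.7%, 17.8% and 16.5% from 15 kb, 28.1%, 26.9% and 25.6% on autosomes, 25.2%, 22.1% and 23.4% with the same number of pairs drawn at each time point, and 34.4%, 34.0% and 31.6% in the stricter list. They were 60.9%, 58.5% and 56.9% with anchors within 1 bin, and from 27.3 to 28.1%, 26.05 to 26.9% and 24.8 to 25.6% with 1 chromosome left out. T0 and T6 had the highest index in each of these, and T6 and T48 exceeded T0 and T48 at equal numbers only.

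The excess of pairs from 500 kb at T48 was 4.94 points from 15 kb, 2.65 in the stricter list, and stayed between 3.601 and 3.64 with 1 chromosome left out. The T6 minus T0 difference was -0.0254 from 15 kb and reversed to 0.123 in the stricter list; the cause was not tested. Spearman's rho of anchor degree (T0 with T6, T0 with T48) was 0.582 and 0.449 from 15 kb, 0.627 and 0.536 on autosomes, 0.584 and 0.459 at equal numbers, 0.388 and 0.140 in the stricter list, and between 0.627 and 0.647 and between 0.524 and 0.537 with 1 chromosome left out. Of the 30 changes of named bins (a bin named in more than 1 comparison counts in each), 29 kept their direction in the stricter list; the bin of chromosome 1 from 5,170,001 turned from a loss to a log2 of 0.091 at T48 over T0, and the cause was not tested. All 30 changes kept it with a pseudocount of 2, from 15 kb and at equal numbers.

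For single interactions, edgeR's 0, 0 and 0 calls (T6 over T0, T48 over T0, T48 over T6) became 1, 94 and 74 in DESeq2, and 0, 1 and 0 for pairs of 25 kb bins; no filter, DESeq2 size factors, offsets per distance class and each library left out gave 0 calls. For windows, the 0, 11 and 8 calls became 20, 527 and 337 in DESeq2. For T48 over T0 and T48 over T6, leaving out 1 library gave between 0 and 0 calls, windows of 100 kb and distances of at least 15 kb gave 0, and windows of 25 kb gave 13 and 5. Without 1 library the log2 ratios of the called windows moved by at most 0.072 and 0.062, with 2 residual degrees of freedom in place of 3; for the other settings the cause was not tested. The 11 and 8 windows were all called again with no filter, with DESeq2 size factors and in DESeq2.

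Replicate numbers were shared between groups, but the labels give no common origin, so the samples share only a number. With the replicate number as a block (replicate block), edgeR called 0, 1 and 1 interactions and 11, 185 and 161 windows, the latter including all 11 and 8 windows called without it. The differences between replicates correlated across interactions at 0.349 for T0 with T6, 0.295 for T0 with T48 and 0.292 for T6 with T48, and 6 of 6 libraries correlated best with one of their own number, a hint from the data and not from the design.

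Not run were a list ranked by the authors' significance value, because the table used here has none, reciprocal overlap of anchors of different size, because all bins are 5 kb, pairs between chromosomes, because 0 are listed, the gene lists and their placement, because no mm9 annotation was used, a pseudocount on the log scale, because counts were tested, and lists without a replicate, because pairs are listed for both replicates jointly. Leaving out a library left a group with 1 sample, assumed to vary like the other groups.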

Other observations

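The counts of bins with many interactions, the tests on the lowest listed counts, on T48 thinned alone and on the coverage of bins with none at T48, and the test on the number of listed chromosome X pairs were chosen only after the results were seen, and the test on the evenness of chromosome X was taken up after that on the number had come out. Bins with at least 50 listed interactions were concentrated on chromosome 1. There were 556 such bins at T0, 515 at T6 and 320 at T48, and chromosome 1 held 349, 333 and 202 of them (62.8%, 64.7% and 63.1%), although it has 7.87% of the bins with any interaction. Chromosome 6 came next with 80, 80 and 42. Of these bins, 443 of those at T6 and 251 of those at T48 also had at least 50 at T0. A bin of this kind at any time point lay in 10 of the 12 windows called at 48 h, 6 of which are on chromosome 1. The share of all 49,387 tested windows with such a bin was not counted, so the 10 have no base rate beside them.

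Bins that had at least 100 interactions at 1 of T0 and T48 and at most 10 at the other numbered 11, all of them on chromosome 1. In 8 the high value was at T48, for example from 67,840,001 (2, 2 and 118 interactions at T0, T6 and T48), from 62,035,001 (9, 6 and 132) and from 19,840,001 (8, 6 and 108). In 3 it was at T0: from 4,125,001 (120, 33 and 5), from 138,430,001 (103, 12 and 8) and from 191,830,001 (105, 11 and 7). The number of chromosome 1 pairs that touch 1 of its 428 bins with at least 50 interactions at any time point changed by -24.2% from T0 to T48, and that of its other pairs by -11.5%. Between 20 and 100 kb the changes were -32.2% and -28.7%. No explanation of this concentration on chromosome 1 was tested.

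Interactions of at least 500 kb made up 3.62 percentage points more of the T48 list than of the T0 list. Thinning argues against a difference in the listed counts of the libraries as the cause. The sequencing depth is not known and interactions were not called again at lower depth, so depth itself stays untested. After thinning both time points to equal counts over adjacent bins, with the higher of both lowest listed counts required, the difference was 4.27 points, between 1.16 and 1.19 times its size before (95% bootstrap interval over chromosomes). This thinned T0 more than T48, which by itself widens the difference. Both T48 libraries alone were also thinned to 87.7%, the larger difference in counts over adjacent bins between T0 and T48 libraries of the same number. The higher lowest counts were again required. The number of long T48 pairs fell to 184,697, below the 219,011 of T0. The difference in share was 3.63 points, against 4.05 points under the same requirement without thinning, so thinning lowered it in part. It was between 0.980 and 1.02 times the 3.62 points of the full lists. The tables argue against a lowest listed count per distance that differs between time points, since the difference was 4.05 points when the higher of both was required without thinning, between 1.11 and 1.12 times its size before (same kind of interval). T48-only long pairs had listed neighbours 1.02 times as often, relative to shuffled pairs, as T0-only long pairs (interval 1.01 to 1.03). This argues against extra ligation products spread evenly at random at T48. Random products that gather in bins of high coverage would have neighbours too, so the test cannot exclude those. A change of the contacts with ATRA or with time in culture, which the design cannot tell apart, may account for the difference. So may a caller that weighs bin coverage differently at each time point, and neither was tested.

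Chromosome X pairs under 20 kb held fewer counts at T48. Fewer copies of the chromosome in the T48 cells may account for it, but the tests went opposite ways: the change was negative in 31 of 31 windows of 5 Mb, with an SD 0.687 times that of autosomal windows (interval 0.510 to 0.866), whereas the number of listed pairs, the first test made, was higher by a log2 of 0.28 (interval 0.26 to 0.29), and still by 0.15 among bins listed at every time point. How the authors' caller treats bin coverage is unknown, which keeps this open. The bias between replicate 1 and replicate 2 libraries stays open too: over autosomal windows its correlation with the change was 0.0694 (Spearman), under the bound of 0.2 set to exclude it, but chromosome X alone differed between replicates by a log2 of -0.20 at T0 and -0.23 at T6, as much as the change itself, and autosomes cannot show that. A biological difference between the time points was not tested.

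In 1494 bins no interaction was listed at 1 time point although at least 20 were listed over the other 2, against 38.4 if interactions were drawn at random. They lacked interactions at T0 in 788 cases, at T6 in 662 and at T48 in 44, and 39.0% lay on chromosome X or 14, which hold 8.60% of the bins compared. Leaving out of the whole bin at that time point may account for them. The 4 flanking bins kept their share of the list, with a median log2 ratio of -0.092 (interval -0.12 to -0.064). Flanking bins would also keep it if the bin alone had low coverage or changed its contacts, so this value cannot tell these apart. Low coverage of the bin could not be told apart from the data: the median bin was at the 36.4th percentile of the highest count with an adjacent bin, between the bounds of 25 and 50 set for either outcome. It was at 36.4 for bins with none at T0, 37.03 at T6 and 13.2 at T48, where the interval of 9.63 to 34.1 over 44 bins includes the bound of 25. Most bins with the largest gains and losses in the report have such a 0, and a biological difference was not tested.

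Of the counts in pairs of at least 2 Mb listed at all 3 time points, the top 20 windows of 1 Mb held 88.7%, and the window of chromosome 1 between 85,000,001 and 86,000,000 alone 57.7%. Replicate 2 held more of them than replicate 1 at each time point, with 64,634 against 24,233 at T0, 63,569 against 25,291 at T6 and 66,499 against 20,659 at T48.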
